A study of Rattus norvegicus with 10 samples.

How the data were processed

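Total RNA was extracted from the lateral part of the left gastrocnemius of 5 aged and 5 young male Sprague-Dawley rats, separate animals with 1 array each, and biotin-labelled complementary RNA was hybridised to expression arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, normalized between arrays by the authors; the submitters' processing notes name RMA, robust multi-array averaging, which corrects background, equalizes distributions between arrays and combines the probes of a probe set, without a version or settings. The array's design, its probe annotation and its genome build were not given in the sources used here, so no coordinates are printed. RMA pulls the distributions of the arrays together, so a change shared by most transcripts would not be seen, and it compresses differences of dim probe sets near background, so fold changes of low genes are understated.

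A deposited table of the series held 43686 probe sets with gene symbols, and a second deposited table held the same intensities for 43685 of them, each of its 10 columns equal to a column of the first. The first gave each column's age group but not its replicate number, and it was used for all tests between groups; the second, whose columns carry replicate numbers, gave the values per replicate and the fits without single arrays. The names of 2 aged columns in the first table contain the word replacement, which the sources used here do not explain. By their values these columns are aged replicates 4 and 5, so fits without them keep aged replicates 1 to 3. Columns were assigned to groups from their labels, and no column was left out. Intensities ranged from 3.16 to 25989 and were log2-transformed without a pseudocount or a filter on dim probe sets. No measure of background or detection came with the values, so no limit could be set from these. The self-test below gives how often changes of 1.5-fold and 2-fold were recovered in simulated data with 5 arrays per group.

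Gene symbols came from the deposited table and were brought up to date through the RefSeq gene table of the rat assembly GRCr8, used for names alone: of 19091 distinct symbols 13892 were current, 3266 were replaced by a current symbol and 1933 were kept as deposited. Another 16184 probe sets carried no symbol, and 22 symbols had been turned into dates and were not named. For a gene with several probe sets, as 5886 genes had, the one with the highest mean over all 10 arrays stood for the gene. Of 172 genes named in the text, 44 passed and had further probe sets: in 19 of these all further probe sets passed in the same direction, in 19 none passed, and no named gene had one that passed in the opposite direction. For 14 named genes (Clrn1, Krt18, RT1-CE5, Cxcl13, Mcm6, Fgf21, Nefm, Ccr2, Fcrl2, Klrd1, Prf1, S100a8, Ccl2 and Drp2) the mean of a group lay below the lowest array median, a log2 intensity of 3.75, so their fold changes rest on a level not shown to be above background.

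Each probe set was fitted with limma (version 3.58.1, in R 4.3.3; lmFit and eBayes, two-sided) on log2 intensity with age group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all 43686 probe sets, with a threshold of 0.05 and, for a second count, a change of at least 1.5-fold. The series' description names a p-value and a fold change as criteria and gives neither, so both thresholds are choices made for these counts. A standard error given with ± beside a log2 fold change is limma's, and adjusted p-values of genes are limma's throughout. Fold changes are ratios of geometric means, given as higher or lower in aged muscle.

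The 46 gene lists, with 997 distinct genes of which 937 were measured, covered the neuromuscular junction, denervation, atrophy, protein breakdown, fibre types, energy metabolism, matrix, immune and other cell types, stress responses and growth signalling. Each list of at least 5 measured genes was tested with limma's camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene, adjusted over the 46 lists, with camera at a correlation estimated per list and limma's fry as alternatives; members past the threshold were counted over all probe sets and again adjusted over the list alone. The shift of a list in an animal is the mean log2 intensity of its genes minus their mean over the young animals. Several lists share genes, such as denervation response with atrophy ligases, or calcium handling with fibre types, and muscle fibres express some markers of other cell types, such as MHC class I genes and Vegfa.

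The spread between animals was compared as the median over probe sets of the log2 ratio of SDs, with an exact two-sided permutation test over all splits of the arrays into 5 and 5, after centring each group. The tests, the thresholds, the lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest increases and 12 largest decreases among named genes past the threshold with no overlap between the groups, up to 3 members of each list past the threshold with the largest changes (2 with the smallest p where none passed), and always Cdkn1a, Myog, Chrna1, Myh7, Myh4, Ppargc1a, Col1a1, Col3a1, Cd68, Cd74, Fbxo32 and Trim63. Of the list members, 25 are given together, apart from their lists; this grouping was made after the values were seen and holds most of the genes whose call was lost without single arrays. Another 15 genes, named in the closing section outside this rule, were chosen after their values were seen.

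The procedure was tested on simulated data built on the real arrays: of 100 probe sets changed 1.5-fold, limma recovered 81 with the right direction, and of 100 changed 2-fold it recovered 93, while 10 unchanged probe sets of the 43686 passed. Of 5 lists shifted by 0.3 on the log2 scale camera called 5, and it called none of 34 lists without a shifted member at an adjusted p under 0.05. The simulation drew genes independently, so it holds no correlation between the genes of a list. It changed 200 probe sets, far fewer than passed in the real data. Its adjusted threshold was thus stricter, and its rates hold for that setting alone. Alternatives were the second deposited table, quantile normalization, centring each array on its median, filters on dim probe sets, a mean over the probe sets of a gene, limma's trended robust variance, array weights, the replicate number as a block, each array left out in turn and, added after the data were seen, leaving out the 2 columns named as replacements. Figures were drawn with matplotlib.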

Results

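Gastrocnemius muscle, a mixed-fibre calf muscle, was taken from 5 aged and 5 young male rats of the outbred Sprague-Dawley stock and profiled on one-colour expression arrays, with 1 array per animal. The aged group was given an age of 24 months and was 28 months old at necropsy, and the young group was given an age of 6 months and was 7 months old at necropsy. The aged rat served as a model of sarcopenia, the loss of muscle mass and strength with age, and the comparison asked which transcripts differed between aged and young muscle. Each array gave an intensity for 43686 probe sets, of which 27502 carried a gene symbol, for 19091 distinct symbols. The median intensity of an array lay between 13.46 and 13.74 in aged and between 13.79 and 13.99 in young animals, without overlap. Every comparison of the groups rested on 5 aged and 5 young arrays. Log2 intensities of any 2 arrays correlated with Pearson's r between 0.977 and 0.995 across probe sets, which are not independent replicates. The first principal component held 53.6% of the variance and placed the 5 young arrays between -42.9 and -27.2, aged replicate 1 at 7.8 and the other 4 aged arrays between 34.7 and 46.8. Aged replicate 1 correlated with the other aged arrays (mean r 0.990) about as closely as with the young ones (mean r 0.990), so its value is given beside several of the gene groups.

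Aged muscle carried far more transcript for Dclk1, embryonic myosin and the alpha subunit of the acetylcholine receptor, and far less for the nuclear receptors Nr4a3 and Nr4a1. Chrna1, the alpha subunit of the muscle acetylcholine receptor, rose 24.5-fold (log2 fold change 4.62 ± 0.25 SE, n = 5 per group, adjusted p = 7.75e-07). Dclk1, a microtubule-associated kinase, rose 33.7-fold, Ctxn3, a small membrane protein, 33.0-fold, and Myh3, the embryonic myosin heavy chain, 29.4-fold. Clrn1, a membrane protein known from sensory hair cells, rose 41.7-fold (log2 fold change 5.38 ± 0.43, adjusted p = 1.68e-05) and the keratin gene Krt18 29.3-fold. The young means of Clrn1 (log2 intensity 3.39) and Krt18 (3.08) lay below the lowest array median (3.75), and without a detection measure their folds and rank are uncertain. RT1-CE5, Cxcl13, Ccl2, Nefm, Fgf21, Mcm6 and Prf1, given below, had such young means too. Emb, a partner of lactate transporters in the membrane, rose 21.7-fold, the phosphatase inhibitor Ppp1r14c 19.6-fold, the tissue kallikrein Klk1 17.1-fold, Sln, an inhibitor of the calcium pump of the sarcoplasmic reticulum, 15.3-fold, the serpin Serpina12 14.8-fold and the transcription factor Runx1 14.7-fold. In the other direction, Nr4a3 fell 14.4-fold (log2 fold change -3.84 ± 0.43, adjusted p = 0.000125), and Nr4a1, which like Nr4a3 is a nuclear receptor that responds to muscle activity, fell 6.18-fold. Sema7a, a membrane-anchored semaphorin, fell 7.53-fold, Tfrc, the receptor for iron-bound transferrin, 6.11-fold, and Slc25a25, a mitochondrial carrier for ATP-magnesium, 5.69-fold. Pfkfb1, an enzyme that sets the level of fructose 2,6-bisphosphate, fell 5.01-fold, Lgi2 4.32-fold, the lactate exporter Slc16a3 4.24-fold, the magnesium transporter Slc41a3 4.20-fold, the arrestin family member Arrdc2 4.05-fold, Apold1 4.02-fold and the MAP kinase phosphatase Dusp1 3.88-fold. With the mean over their probe sets the log2 fold change was 2.28 against 5.07 for Dclk1, 2.98 against 4.88 for Myh3, 2.29 against 4.10 for Klk1 and -2.09 against -3.84 for Nr4a3. These 12 increases and 12 decreases were the largest among named genes that passed with no overlap between the groups. The absence of overlap was thus part of the rule that chose them. Their largest adjusted p was 0.000906.

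In all, 6536 of 43686 probe sets (15%) differed at an adjusted p under 0.05 in limma's moderated test, 3535 of them higher and 3001 lower in aged muscle. This balance turned with the scaling of the arrays, to 3057 higher and 3334 lower with quantile normalization and 3973 higher and 2330 lower with median centring. At a change of at least 1.5-fold, 2299 probe sets remained, 1503 higher and 796 lower. Of 19049 genes, each taken by its brightest probe set, 4280 passed with p adjusted over all probe sets, 2623 higher and 1657 lower, whereas of the 16184 probe sets without a gene symbol 1144 passed, 388 higher and 756 lower. The 2 groups did not overlap in 5130 probe sets (11.7%), against 0.794% expected by chance for 5 against 5 values.

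**Figure D1:**
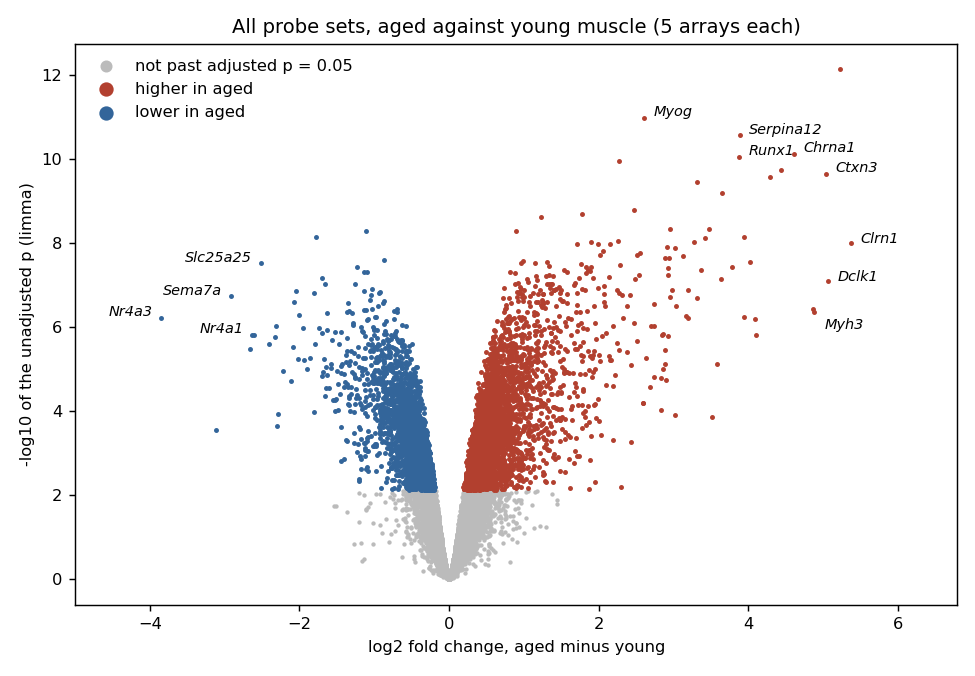
Each point is 1 of the 43686 probe sets, with the log2 fold change (aged minus young) on the horizontal axis and the negative log10 of limma's unadjusted p on the vertical axis; red points were higher and blue points lower at an adjusted p under 0.05. Of the 6536 coloured points 3535 lie to the right and 3001 to the left, a balance that quantile normalization turned to 3057 and 3334.

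Of 46 gene lists fixed in advance, limma's camera called 14 higher and 11 lower in aged muscle, with a preset correlation between genes of 0.01. With the correlation estimated from each list, camera called 0 lists at an adjusted p under 0.05 and 6 at an unadjusted p under 0.05, and fry, which tests whether the genes of a list move one way, called 17 higher and 9 lower. In other splits of the 10 arrays into 5 and 5, which mix aged and young animals on both sides, camera called a median of 14 lists and at most 27. With age group as a further term of the fit these splits still gave a median of 13. The preset-correlation p-values of lists thus understate chance, and the counts of members called in limma's fit are given beside them. Of all 19049 genes 22.5% passed, 2623 higher and 1657 lower, so a list with shares near these does not stand out by its counts.

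Genes that adult muscle switches on after loss of nerve input were the group with the largest shift. Of 19 measured genes of the denervation response, 12 rose and 7 did not pass (14 rose when adjusted over the list alone), with a median log2 fold change of 1.99. Myog, the myogenic factor induced in denervated fibres, rose 6.10-fold (log2 fold change 2.61 ± 0.12, adjusted p = 2.31e-07), and Gadd45a, a stress-induced gene, rose 10.3-fold. Myh3, Sln and Runx1, already named, belong to this list too, while the log2 fold changes of Fbxo32 (0.08 ± 0.17, adjusted p = 0.802) and Trim63 (0.36 ± 0.14, adjusted p = 0.109), ubiquitin ligases of muscle atrophy, did not pass. Camera called the list higher (adjusted p = 1.33e-11; adjusted p = 0.19 with an estimated correlation). Among 16 genes of the acetylcholine receptor and the neuromuscular junction, 8 rose, 1 fell and 7 did not pass, the same counts adjusted over the list alone. For the acetylcholine receptor and neuromuscular junction, camera called the list higher (adjusted p = 0.000177; adjusted p = 0.19 with an estimated correlation). Chrng, the gamma subunit of the fetal receptor, rose 9.04-fold and the delta subunit gene Chrnd 5.54-fold. The 2 lists were higher in 5 of 5 aged animals than in any young one, with aged replicate 1 the lowest of the aged animals for the denervation response (mean log2 shift from young 1.5, against 2.00 to 2.33 in the others) and for the junction (0.70, against 0.98 to 1.15). The call of Trim63 depended on 1 array, since without aged replicate 4 its adjusted p was 0.0283. Of 15 potassium, sodium and chloride channel genes of muscle, 1 rose, 7 fell and 7 did not pass (2 rose and 8 fell adjusted over the list alone). Kcnn3, a calcium-activated potassium channel that denervated fibres express, was the gene that rose (3.98-fold), while Kcna5, a voltage-gated potassium channel, fell 2.13-fold and Atp1b2, a subunit of the sodium pump, 2.12-fold. For potassium, sodium and chloride channels of muscle, camera called the list lower (adjusted p = 0.00806; adjusted p = 0.19 with an estimated correlation). The channel shift was -0.12 in aged replicate 1 and -0.30 to -0.21 in the other aged animals. Of 19 Schwann cell and nerve genes, 2 rose and 1 fell, also adjusted over the list alone. Among them were Cnp, an enzyme of myelin (3.45-fold higher), and Nefm, a neurofilament (2.40-fold higher). Camera did not call the list (adjusted p = 0.312), and without aged replicate 1, 4 genes rose.

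**Figure D2:**
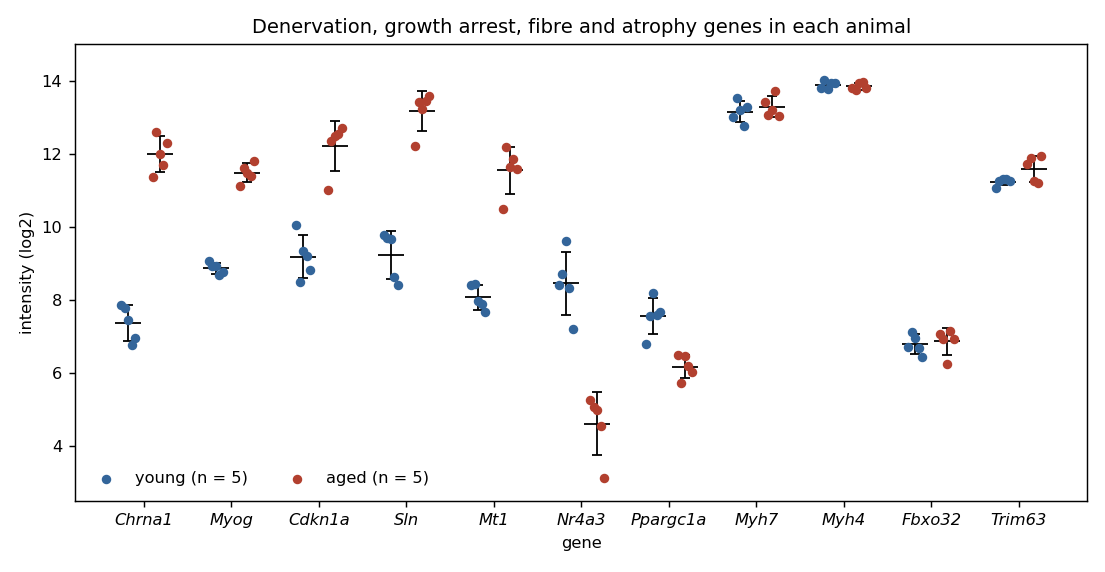
Log2 intensity of 11 genes in each animal, with young animals in blue and aged animals in red (n = 5 each); black bars give the mean and SD of each group. The aged animals lie above the young ones without overlap for Chrna1, Myog, Cdkn1a, Sln and Mt1 and below them for Nr4a3 and Ppargc1a, while the groups overlap for Myh7, Myh4, Fbxo32 and Trim63.

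Genes of growth arrest rose in part, as did some of muscle regeneration. Among 21 genes of the p53 pathway and senescence, 10 rose, 3 fell and 8 did not pass, the same counts adjusted over the list alone. For p53 and senescence, camera called the list higher (adjusted p = 0.00189; adjusted p = 0.34 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 8.18-fold (log2 fold change 3.03 ± 0.32, adjusted p = 8.07e-05), and Cdkn2b, another inhibitor of cyclin-dependent kinases, rose 4.39-fold. Cdkn1a and Gadd45a belong to the denervation list too, and the median log2 fold change of the p53 list was 0.23. Of 23 genes of insulin, IGF and growth signalling, 10 rose, 3 fell and 10 did not pass (13 rose and 5 fell adjusted over the list alone). Fst, the antagonist of myostatin and activins, rose 9.73-fold, Igf2, a fetal growth factor, rose 4.98-fold, and Mstn, which encodes myostatin, the inhibitor of muscle growth, fell 2.80-fold. For insulin, IGF and growth signalling, camera called the list higher (adjusted p = 0.00851; adjusted p = 0.34 with an estimated correlation). Restricted to probe sets brighter than the median, this list was not called (adjusted p = 0.0502). In aged replicate 1 the shift was 0.39 for p53 and senescence and 0.18 for growth signalling, against 0.57 to 0.85 and 0.46 to 0.58 in the other aged animals. Of 19 satellite cell and regeneration genes, 7 rose, 1 fell and 11 did not pass (8 rose and 3 fell adjusted over the list alone). The myogenic factor Myf5 rose 4.25-fold and Mymk, which encodes the fusion protein myomaker, 6.05-fold. Myog, a member of the denervation list, belongs to this list too. Camera missed the threshold for this list (adjusted p = 0.0674), passing it without aged replicate 1 (adjusted p = 0.0406) or aged replicate 2 (adjusted p = 0.0383). Fry called it higher (adjusted p = 0.00118), its median log2 fold change was 0.07, and 4 genes rose without young replicate 5 or aged replicate 3. Of 23 cell cycle genes, 4 rose and 19 did not pass, also adjusted over the list alone, Pcna, a sliding clamp of DNA replication, by 1.5-fold and Mcm6, a helicase subunit, by 1.46-fold. Camera did not call the cell cycle list (adjusted p = 0.0845) but called it without aged replicate 2 (adjusted p = 0.0221), without the 2 aged arrays marked as replacements (adjusted p = 0.0323), with quantile normalization (adjusted p = 0.04) and with the mean over the probe sets of a gene (adjusted p = 0.023). Its shift was 0.46 in aged replicate 1 and 0.02 to 0.18 in the other aged animals, and without aged replicate 1 the mean log2 fold change of the list was 0.10 rather than 0.17 (adjusted p = 0.381). For the satellite cell list the shift of aged replicate 1 was 0.27, against 0.56 to 0.65.

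Genes of protein breakdown were split between the proteasome, which rose, and the atrophy ligases, which went both ways. Of 30 proteasome subunit genes, 21 rose and 9 did not pass (26 rose adjusted over the list alone), with a median log2 fold change of 0.35. Psmb3 rose 1.61-fold, Psma2 1.58-fold and Psma4 1.52-fold. For proteasome genes, camera called the list higher (adjusted p = 6.57e-10; adjusted p = 0.34 with an estimated correlation). The mean shift of the proteasome list was 0.37 ± 0.21 (SD, n = 5) in aged animals, from 0.08 in aged replicate 4 to 0.65 in aged replicate 5. Of 18 ubiquitin ligases of muscle atrophy and FoxO targets, 4 rose, 5 fell and 9 did not pass (5 rose and 5 fell adjusted over the list alone). Without young replicate 1, young replicate 3 or any of aged replicates 2, 3 and 5, 2 of them rose. Fbxo30, a ligase subunit induced in wasting muscle, rose 4.75-fold, while Mul1, a mitochondrial ligase, fell 1.76-fold and Ddit4, an inhibitor of mTORC1, fell 2.72-fold. The list was not called (camera, adjusted p = 0.718), and the sign of its mean turned under several settings. Of 24 autophagy and lysosome genes, 9 rose and 15 did not pass (12 rose adjusted over the list alone). The lysosomal proteases Ctsl and Ctsb rose 3.03-fold and 1.70-fold, and the autophagy receptor Sqstm1 rose 1.63-fold. For autophagy and lysosome, camera called the list higher (adjusted p = 0.00025; adjusted p = 0.19 with an estimated correlation). Of 20 genes of the unfolded protein and integrated stress response, 5 rose and 2 fell (6 and 2 adjusted over the list alone), among them Herpud1, a component of endoplasmic reticulum degradation, 1.88-fold higher, and the stress hormone Fgf21, 1.58-fold higher. Camera missed the threshold for this list (adjusted p = 0.0693), passing it without young replicate 3 (adjusted p = 0.0382) or aged replicate 3 (adjusted p = 0.0491), and fry called it higher (adjusted p = 0.00473). Of 19 heat shock and chaperone genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.718). The small heat shock genes Hspb8 and Hspb7 were the ones that rose, 1.97-fold and 1.78-fold, and 0 fell without aged replicate 2 or without the replacement arrays.

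Most genes of fibre type did not pass. The slow myosin gene Myh7 (log2 fold change 0.13 ± 0.15, adjusted p = 0.629) and the brightest probe set of the fast myosin gene Myh4 (-0.05 ± 0.07, adjusted p = 0.726) did not pass. Of the other 2 probe sets of Myh4, a dim one passed (-0.44 ± 0.12, adjusted p = 0.0251) and a bright one did not (-0.08 ± 0.10, adjusted p = 0.650). Myh1, another fast myosin, fell 1.77-fold on its brightest probe set. None of its other 3 probe sets passed, and the mean over the 4 gave a log2 fold change of -0.29 against -0.83. Of 16 fast fibre genes, 6 fell and 10 did not pass (7 fell adjusted over the list alone), among them Mybpc2, the fast isoform of myosin-binding protein C, 1.46-fold. For fast fibre genes, camera called the list lower (adjusted p = 0.0201; adjusted p = 0.34 with an estimated correlation). The median log2 fold change of the fast list was -0.06, and its mean was -0.20 ± 0.03 (SD, n = 5) over the aged animals. Of 14 slow fibre genes, 2 rose and 1 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.244); without young replicate 2, 4 rose. Csrp3, a Z-disc protein that responds to stretch, rose 2.58-fold and Casq2, the slow isoform of calsequestrin, 2.03-fold. Of 16 calcium handling genes, 3 rose and 4 fell (3 and 8 adjusted over the list alone), Sln and Casq2 among the former and Jph2, a protein of the triad junction, 1.72-fold among the latter. The median of this list (-0.13) and its mean (0.14) differed in sign, camera placed it lower without calling it (adjusted p = 0.176), and without aged replicate 1, 7 genes fell.

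Many energy metabolism genes fell in aged muscle, from glycogen breakdown and glycolysis to the respiratory chain. Of 20 glycolysis and glycogen genes, 16 fell and 4 did not pass (1 rose and 17 fell adjusted over the list alone), with a median log2 fold change of -0.69. Phkg1 and Phka1, subunits of phosphorylase kinase, fell 2.46-fold and 2.19-fold, and Pfkm, the muscle phosphofructokinase, fell 1.86-fold. For glycolysis and glycogen, camera called the list lower (adjusted p = 3.81e-09; adjusted p = 0.32 with an estimated correlation). Of 35 complex I genes, 19 fell and 16 did not pass (1 rose and 27 fell adjusted over the list alone), Ndufs1 by 1.62-fold, Ndufa8 by 1.54-fold and Ndufa9 by 1.47-fold. For complex I, camera called the list lower (adjusted p = 6.07e-10; adjusted p = 0.34 with an estimated correlation). Of 37 genes of complexes II to V, 1 rose, 21 fell and 15 did not pass (1 and 28 adjusted over the list alone). The electron carrier cytochrome c, Cycs, fell 1.59-fold, and Cox8a, a subunit of cytochrome c oxidase, was the gene that rose (1.40-fold; camera, list lower, adjusted p = 1.64e-08; adjusted p = 0.39 with an estimated correlation). Of 23 genes of the citric acid cycle and pyruvate dehydrogenase, 1 rose, 13 fell and 9 did not pass (1 and 18 adjusted over the list alone), with Pdk2, a kinase that inhibits pyruvate dehydrogenase, 1.84-fold lower and Idh3a, a subunit of isocitrate dehydrogenase, 1.79-fold lower. For the citric acid cycle and pyruvate dehydrogenase, camera called the list lower (adjusted p = 4.47e-07; adjusted p = 0.34 with an estimated correlation). Ppargc1a, a coactivator that drives mitochondrial biogenesis, fell 2.61-fold (log2 fold change -1.39 ± 0.21, adjusted p = 0.000938), its relative Ppargc1b fell 1.67-fold, and of 11 genes of mitochondrial biogenesis and dynamics 3 fell (4 adjusted over the list alone; camera, adjusted p = 0.0118; adjusted p = 0.34 with an estimated correlation). With the mean over its 3 probe sets the log2 fold change of Ppargc1a was -0.71. Of 24 genes of fatty acid uptake and oxidation, 1 rose, 5 fell and 18 did not pass (1 and 8 adjusted over the list alone). Decr1, an auxiliary enzyme of beta-oxidation, was the gene that rose (1.53-fold), and Ppara, a nuclear receptor for fatty acids, fell 1.44-fold from a low intensity. For fatty acid uptake and oxidation, camera called the list lower (adjusted p = 0.0277; adjusted p = 0.64 with an estimated correlation), and fry gave adjusted p = 0.262. Aged replicate 1 did not share the shift of the respiratory chain: its mean log2 shift was -0.05 for complex I, -0.01 for complexes II to V, -0.03 for the citric acid cycle and 0.17 for fatty acid oxidation, against -0.54 to -0.31, -0.43 to -0.23, -0.58 to -0.38 and -0.36 to -0.05 in the other aged animals. For glycolysis it was -0.25 against -0.82 to -0.51, and for mitochondrial biogenesis -0.13 against -0.48 to -0.31. Counts in these lists changed in both directions with the arrays used. Without aged replicate 1, 27 genes fell in complex I, 28 in complexes II to V and 18 in the citric acid cycle. Leaving out the 2 replacement arrays keeps 3 aged animals, aged replicate 1 among them. In that fit 9 genes fell in complex I, 3 in complexes II to V, 5 in the citric acid cycle and 1 in fatty acid oxidation. In complexes II to V, 13 fell without young replicate 1 or 3, 12 without young replicate 5 or aged replicate 4, 10 without aged replicate 5 and 9 without young replicate 4 or aged replicate 2. In fatty acid oxidation 10 fell without aged replicate 1, 3 without young replicate 1 and 2 without any of young replicates 2 to 5 or aged replicates 2, 3 and 5. Camera lost the fatty acid list without young replicate 2 (adjusted p = 0.0598), young replicate 3 (adjusted p = 0.0591), aged replicate 2 (adjusted p = 0.0856) or aged replicate 3 (adjusted p = 0.128).

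Ribosomal protein genes of the cytosol rose, all but 5 of them, while 13 of 38 genes of mitochondrial ribosomes fell. Of 64 cytosolic ribosomal protein genes, 59 rose and 5 did not pass (61 rose adjusted over the list alone), with a mean shift of 0.48 ± 0.14 (SD, n = 5) in aged animals and an SD of 0.03 in young ones. Rpl3, whose product lies near the peptidyl transferase centre, rose 4.16-fold, Rps21 1.91-fold and Rpl31 1.79-fold. For cytosolic ribosomal proteins, camera called the list higher (adjusted p = 1.58e-25; adjusted p = 0.32 with an estimated correlation). Of 38 mitochondrial ribosomal protein genes, 2 rose, 13 fell and 23 did not pass (3 and 17 adjusted over the list alone). Mrpl15 fell 1.38-fold, and Mrpl45 rose 1.71-fold against the direction of its list. For mitochondrial ribosomal proteins, camera called the list lower (adjusted p = 0.00147; adjusted p = 0.5 with an estimated correlation), and fry gave adjusted p = 0.0607. Aged replicate 1 had the smallest shift of the cytosolic list among aged animals (0.25, against 0.45 to 0.61) and lay on the other side of young for the mitochondrial list (0.05, against -0.28 to -0.11). The number of mitochondrial ribosomal genes that fell was 7, 8, 6, 5 and 5 without young replicates 1 to 5 in turn. Without aged replicate 1 it was 18, without aged replicate 2 it was 4, and without aged replicate 4 or 5 it was 6. Without the replacement arrays it was 2.

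**Figure D3:**
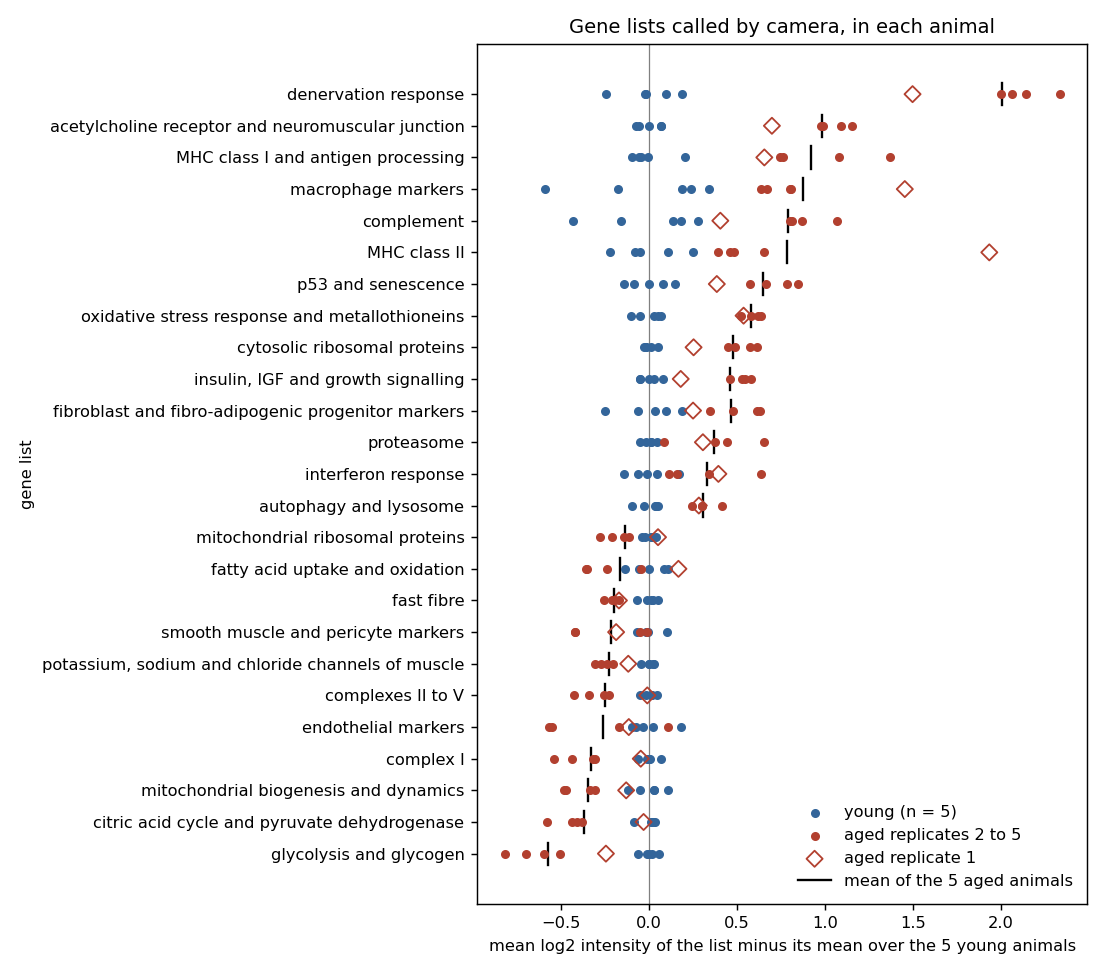
Mean log2 intensity of each of the 25 lists that camera called, in each animal, relative to the mean of the 5 young animals (horizontal axis, log2); blue points are young animals, red points aged replicates 2 to 5, open diamonds aged replicate 1, and black ticks the mean of the 5 aged animals. Aged replicate 1 lies closest to young for most lists, as for the denervation response (1.5), and above all other animals for MHC class II (1.93) and macrophage markers (1.45).

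Many genes of macrophages, complement and antigen presentation rose in aged muscle. Of 25 macrophage markers, 13 rose and 12 did not pass (15 rose adjusted over the list alone), with a median log2 fold change of 0.70. For macrophage markers, camera called the list higher (adjusted p = 1.27e-06; adjusted p = 0.34 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose 7.59-fold, the inhibitory Fc receptor Fcgr2b 4.83-fold and the lysozyme Lyz2 3.68-fold. Cd68 rose 1.98-fold (log2 fold change 0.98 ± 0.29, adjusted p = 0.035), a call lost without young replicate 2 (adjusted p = 0.0582), 4 (adjusted p = 0.091) or 5 (adjusted p = 0.087) and with quantile normalization (adjusted p = 0.0532). Of 17 complement genes, 11 rose and 6 did not pass (14 rose adjusted over the list alone), C4b by 3.47-fold and C1qa by 2.28-fold. For complement, camera called the list higher (adjusted p = 1.3e-05; adjusted p = 0.32 with an estimated correlation). Of 17 genes of MHC class I and antigen processing, 12 rose and 5 did not pass (13 rose and 1 fell adjusted over the list alone); the class I gene RT1-CE5 rose 12.1-fold and the immunoproteasome subunits Psmb8 and Psmb9 rose 3.66-fold and 3.29-fold. For MHC class I and antigen processing, camera called the list higher (adjusted p = 2.3e-06; adjusted p = 0.31 with an estimated correlation). Of 11 MHC class II genes, 4 rose and 7 did not pass (5 rose adjusted over the list alone), among them Cd74, the invariant chain, 2.84-fold (log2 fold change 1.5 ± 0.30, adjusted p = 0.00481), and the class II genes RT1-Da and RT1-Bb, 3.28-fold and 3.21-fold. For MHC class II, camera called the list higher (adjusted p = 0.0161; adjusted p = 0.46 with an estimated correlation), and fry gave adjusted p = 0.0606. Aged replicate 1 stood above the other aged animals for macrophage markers (mean log2 shift 1.45, against 0.64 to 0.81) and MHC class II (1.93, against 0.39 to 0.65) and below them for complement (0.40, against 0.80 to 1.07). Of 31 genes of the interferon response, 7 rose and 24 did not pass (12 rose adjusted over the list alone), with Cxcl9, a chemokine induced by interferon gamma, 2.32-fold higher and the transcription factor Irf1 1.81-fold higher. For the interferon response, camera called the list higher (adjusted p = 0.00267; adjusted p = 0.39 with an estimated correlation). Without the replacement arrays 6 complement genes and 4 interferon genes rose, and without young replicate 1 or young replicate 2, 4 interferon genes rose; restricted to probe sets brighter than the median, MHC class II was not called (adjusted p = 0.0588).

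Some genes of secreted signals and single markers of lymphocytes and granulocytes were called. Of 35 cytokine and chemokine genes, 11 rose, 1 fell and 23 did not pass, the same counts adjusted over the list alone, with Cxcl13, a chemokine for B cells, 4.11-fold higher, Ccl5, a chemokine of T cells and macrophages, 2.67-fold higher and Il15, a cytokine that muscle fibres make, 2.87-fold lower. Camera missed the threshold for this list (adjusted p = 0.0553), passing it without young replicate 3 (adjusted p = 0.035), aged replicate 2 (adjusted p = 0.0379), 3 (adjusted p = 0.0463) or 5 (adjusted p = 0.0268), with quantile normalization (adjusted p = 0.018) and with a trended robust variance (adjusted p = 0.0485). Fry called the cytokine list higher (adjusted p = 0.0011). In this list 7 genes rose without young replicate 4 or young replicate 5. Of 17 acute phase genes and NF-kB targets, 6 rose and 2 fell (7 and 2 adjusted over the list alone), among them the NF-kB subunit gene Nfkb2, 2.55-fold higher, Nfkbie, an inhibitor of NF-kB, 2.34-fold higher, and the transcription factor Cebpd, 2.35-fold lower (camera, adjusted p = 0.132; fry, higher, adjusted p = 0.0105). Of 23 T and NK cell markers, 3 rose (5 adjusted over the list alone), and camera called the list only without aged replicate 1 (adjusted p = 0.0407) or aged replicate 2 (adjusted p = 0.0356) among the arrays left out in turn (adjusted p = 0.0699 with all 10). It also called the T and NK cell list with quantile normalization (adjusted p = 0.0295) and array weights (adjusted p = 0.0484). Leaving out young replicate 1, 2, 3 or 5 left 1 T and NK cell gene that rose, and leaving out aged replicate 1 gave 5. Of 13 B and plasma cell markers, 1 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.992); the rise was lost without any of young replicates 1 to 5 or aged replicates 2, 3 and 4. Of 18 neutrophil and mast cell markers, 3 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.799), and 1 rose without young replicate 5 or without the replacement arrays. Of 15 myokines and secreted factors of muscle, 4 rose and 3 fell (4 and 5 adjusted over the list alone; camera, adjusted p = 0.799), and 2 rose without the replacement arrays.

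The main collagen genes did not move together, in contrast to some matrix and fibroblast genes. Col1a1, the alpha 1 chain of type I collagen, had a log2 fold change of -0.44 ± 0.14 that did not pass (adjusted p = 0.0571), whereas its other probe set passed (-0.67 ± 0.17, adjusted p = 0.0176). Col3a1, of type III collagen, passed narrowly in the other direction (0.44 ± 0.14, adjusted p = 0.0483). Neither call was stable. Col1a1 passed without aged replicate 4 (adjusted p = 0.00155), without the replacement arrays (adjusted p = 0.0068) and with quantile normalization (adjusted p = 0.0396) and with the mean over its probe sets (adjusted p = 0.0232). With quantile normalization the Col3a1 call was lost (adjusted p = 0.119). The Col3a1 call was lost without any of young replicates 1, 3, 4 and 5 or aged replicates 1, 3, 4 and 5, with adjusted p from 0.0501 to 0.117. Of 33 collagen and extracellular matrix genes, 6 rose, 1 fell and 26 did not pass (6 and 2 adjusted over the list alone), among them Postn, the matricellular protein periostin, 3.88-fold, Loxl1, an elastin crosslinking enzyme, 1.93-fold, and the proteoglycan Bgn 1.81-fold (camera, adjusted p = 0.275). Without aged replicate 4, as without the replacement arrays, 4 rose and 3 fell. Of 20 genes of matrix remodelling and fibrosis signalling, 6 rose and 3 fell (7 and 4 adjusted over the list alone), with Ltbp1, which holds latent TGF-beta in the matrix, 5.87-fold higher and Tgfb1 2.54-fold higher (camera, adjusted p = 0.38). Of 19 markers of fibroblasts and fibro-adipogenic progenitors, 6 rose and 13 did not pass (8 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.0118; adjusted p = 0.4 with an estimated correlation). S100a4, a calcium-binding protein of fibroblasts and immune cells, rose 13.8-fold and Dpt, the matrix protein dermatopontin, 2.99-fold; 3 fibroblast genes rose without young replicate 4, young replicate 5 or aged replicate 3. Of 13 tendon and cartilage markers, 2 rose and 6 fell (2 and 7 adjusted over the list alone), Cilp by 3.57-fold upward and Chad by 2.42-fold downward. Camera missed the threshold for this list (adjusted p = 0.0697), passing it without young replicate 3 (adjusted p = 0.0482) or aged replicate 4 (adjusted p = 0.0313) and with median centring (adjusted p = 0.0419), and fry called it lower (adjusted p = 0.0227). In this list 3 genes fell without young replicate 5, aged replicate 3 or aged replicate 5.

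Some markers of blood vessels fell and some of fat rose, but most of either kind did not pass. The median log2 fold change of the adipocyte list was 0.11. Of 17 endothelial markers, 4 fell and 13 did not pass (1 rose and 6 fell adjusted over the list alone), Vegfa, a vascular growth factor that muscle fibres also secrete, by 2.69-fold, Nos3, the endothelial nitric oxide synthase, by 2.13-fold and the VEGF receptor Flt1 by 1.73-fold. For endothelial markers, camera called the list lower (adjusted p = 0.0348; adjusted p = 0.57 with an estimated correlation), and fry gave adjusted p = 0.186. For Vegfa the other of its 2 probe sets did not pass, and the mean over both gave a log2 fold change of -0.74 against -1.43. The endothelial shift was -0.26 ± 0.29 (SD, n = 5), lower than in every young animal in 4 of 5 aged animals. Camera lost the endothelial list without young replicate 2 (adjusted p = 0.0723), aged replicate 2 (adjusted p = 0.0975) or aged replicate 5 (adjusted p = 0.0798). Of 14 smooth muscle and pericyte markers, 6 fell and 8 did not pass, also adjusted over the list alone, with the smooth muscle genes Actg2, Cnn1 and Tagln 1.59-fold, 1.57-fold and 1.42-fold lower. For smooth muscle and pericyte markers, camera called the list lower (adjusted p = 0.0253; adjusted p = 0.5 with an estimated correlation), and fry gave adjusted p = 0.0765. Camera lost this list without young replicate 2 (adjusted p = 0.0596) or aged replicate 5 (adjusted p = 0.0747), and 3 of its genes fell without young replicate 1, young replicate 3, aged replicate 2 or the replacement arrays. Of 19 adipocyte markers, 4 rose and 1 fell (4 and 2 adjusted over the list alone), with the lipogenic genes Scd and Thrsp 4.73-fold and 3.53-fold higher and the lipid droplet gene Cidea 3.88-fold higher. Camera missed the threshold for the adipocyte list (adjusted p = 0.0699), passing it without young replicate 3 (adjusted p = 0.0482), aged replicate 2 (adjusted p = 0.0221) or aged replicate 5 (adjusted p = 0.0408). Of 8 red blood cell markers, 1 fell, also adjusted over the list alone, Bpgm, an enzyme of 2,3-bisphosphoglycerate synthesis, by 1.98-fold (camera, adjusted p = 0.244); without aged replicate 3, 2 fell and camera called the list (adjusted p = 0.0355).

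Genes of detoxification and of metal binding were higher as a group in 5 of 5 aged animals than in any young one. Of 25 genes of the oxidative stress response and metallothioneins, 13 rose, 1 fell and 11 did not pass (14 and 3 adjusted over the list alone), with a mean shift of 0.58 ± 0.05 (SD, n = 5) that aged replicate 1 shared (0.54). Without that replicate 13 rose and 4 fell. The metallothionein gene Mt1 rose 11.2-fold (log2 fold change 3.48 ± 0.26, adjusted p = 1.27e-05), the glutathione transferase gene Gsta3 4.85-fold and the quinone reductase gene Nqo1 3.42-fold. For the oxidative stress response and metallothioneins, camera called the list higher (adjusted p = 0.000191; adjusted p = 0.19 with an estimated correlation). Of 9 polyamine genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera, adjusted p = 0.624). Sat1, which acetylates spermidine and spermine for export, rose 5.70-fold, while Amd1, needed for their synthesis, and Smox, spermine oxidase, fell 1.79-fold and 1.64-fold; the median (-0.15) and mean (0.13) of this list differed in sign. Of 18 circadian clock genes, 1 rose and 6 fell (2 and 6 adjusted over the list alone; camera, adjusted p = 0.0967, and adjusted p = 0.0349 with quantile normalization; fry, lower, adjusted p = 0.0438). The repressor gene Nfil3 fell 2.12-fold and the nuclear receptor gene Rora 1.44-fold.

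A further 25 members of these lists passed with all 10 arrays, and 13 of them lost their call without at least 1 single array. Igha, the heavy chain of immunoglobulin A, passed as 3.87-fold higher on 1 of its 5 probe sets. None of the other 4 passed, and the log2 fold change was 1.95 for the 1 and 0.34 for the mean of the 5. Aged replicates 1 and 5 (log2 intensity 5.44 and 5.61) lay near the young mean (5.28). Angptl4, an inhibitor of lipoprotein lipase, rose 3.70-fold, the monocyte chemokine Ccl2 2.93-fold and Cfd, complement factor D, 2.46-fold. The interferon-induced Gbp2 rose 2.23-fold, the mast cell proteases Cpa3 and Cma1 1.92-fold and 1.67-fold, and the NK cell gene Prf1 1.37-fold. The neutrophil gene S100a8 and the NK cell gene Klrd1 passed as higher and Drp2, a dystrophin relative of Schwann cells, as lower, with both group means below the array medians, so no fold is given. Smoc2, a matrix protein, rose 1.58-fold and Ube2c, a mitotic ubiquitin-conjugating enzyme, 1.36-fold. Among the 13 that fell, Chac1, a target of the integrated stress response, fell 2.72-fold, the muscle fructose bisphosphatase Fbp2 2.18-fold, the heat shock gene Hspa1a 2.15-fold and the proteoglycan Kera 2.15-fold. The mitochondrial genes Acadm, Fh, Ckmt2, Atp5mc1, Mrpl4 and Mfn1 fell 1.46-fold, 1.46-fold, 1.45-fold, 1.40-fold, 1.40-fold and 1.38-fold. The clock gene Per1 fell 1.37-fold and the B cell kinase Blk 1.21-fold. Of the 10 fits that each left out 1 array, Igha and Mrpl4 lost their call in 8, Klrd1 and Prf1 in 7, Blk and Smoc2 in 6, Ccl2, Gbp2 and Per1 in 4, Cma1 and S100a8 in 3, Hspa1a in 2 and Ube2c in 1. Without young replicates 1 to 5 in turn, 9, 7, 5, 8 and 10 of the 25 calls were lost, and without aged replicates 1 to 5, 0, 8, 6, 5 and 5, with adjusted p up to 0.108. Without the replacement arrays, which leaves 3 aged animals, 18 of the 25 calls were lost (adjusted p up to 0.195). Median centring ended the calls of Blk (adjusted p = 0.0592) and Mrpl4 (adjusted p = 0.0648), quantile normalization that of Smoc2 (adjusted p = 0.0582) and the mean over its probe sets that of Igha (adjusted p = 0.0954).

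Over all probe sets, aged animals did not differ from each other detectably more than young animals did, but among the brighter probe sets they did. Over probe sets, the median SD of log2 intensity was 0.138 in aged and 0.125 in young animals. The median over probe sets of the ratio of the 2 SDs was 1.13, a log2 ratio of 0.17. An exact two-sided permutation test over all splits of the 10 arrays into 5 and 5 gave p = 0.103. Among probe sets brighter than the median the log2 ratio was 0.39, which passed (exact permutation p = 0.0238). Over all probe sets the log2 ratio was -0.02 without the replacement arrays. Leaving out single arrays, it ran from 0.08 without aged replicate 4 to 0.28 without young replicate 5. SDs of fewer arrays tend to come out smaller, so groups of unequal size shift the ratio by themselves. It fell without each aged array and rose without each young array.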

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

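The search for single animals far from the rest of their group and the counts over other splits of the arrays were planned, the fit of these splits with an age term was added after the counts had been seen, all other tests were chosen after the values were seen, and the criteria for lymphoid tissue and for a mixture were reworded once their values were known.

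For every gene named in the text, every gene list and 3 summaries of each array, the gap between the most extreme animal of a group and its neighbour was set against the group's range, and 31 of 442 groups of 5 passed Dixon's critical value of 0.71, where chance alone passes about 1 in 20. Among the genes were 15 chosen after their values were seen, 4 of them because aged replicate 1 stood apart; without the 15, 27 of 412 groups passed, 14 of them by aged replicate 1. This animal had the highest log2 intensity of its group for Lyz2 (12.87, against 10.75 to 10.89 in the other aged animals), Cd68 (8.28, against 6.65 to 6.84), Cd74 (12.22, against 10.27 to 10.70), RT1-Da (10.95, against 8.54 to 8.78), RT1-Bb (9.74, against 7.13 to 7.87), Amd1 (8.57, against 7.91 to 7.99) and the mitochondrial genes Fh (11.80, against 11.05 to 11.21) and Acadm (12.83, against 11.95 to 12.19). It had the lowest for Sln (12.21, against 13.22 to 13.58), Cdkn1a (10.99, against 12.35 to 12.69) and S100a4 (10.08, against 11.64 to 12.13). Its mean log2 shift from young stood apart for MHC class II (1.93, against 0.39 to 0.65), macrophage markers (1.45, against 0.64 to 0.81) and satellite cell genes (0.27, against 0.56 to 0.65).

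Aged replicate 1 lay between the groups over the genes that differed with age, and above the other aged animals for macrophage and MHC class II genes. A young animal under a wrong label was argued against by its median position, 0.52 on a scale from young (0) to the other aged animals (1) over 917 probe sets changed at least 2-fold in a fit without it, where the young animals ran from -0.12 to 0.10 and the other aged animals from 0.93 to 1.2. A mixture with young RNA cannot be told apart, because the undiluted level of this animal is not known and its MHC class II shift of 1.93, above the 0.65 of the next aged animal, may be its own. Lymphoid tissue in the dissected muscle would also bring lymphocytes, yet the T and NK cell shift of this animal (0.033, against 0.12 to 0.52) and its B and plasma cell shift (-0.03, against 0.03 to 0.28) lay below those of the other aged animals. A smaller response to age with more macrophages in this 1 animal may be biological and stays open and untested.

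Most cytosolic ribosomal protein genes rose while many glycolysis and respiratory chain genes fell. With quantile normalization or median centring the mean log2 fold changes of the 4 lists (ribosomal, complex I, complexes II to V, glycolysis) kept their direction and at least 88.1% of their size. Both were applied to values already normalized by the authors, with array medians of 3.751 to 3.806 on the log2 scale. They could move the lists only little, so they cannot decide whether the authors' normalization shaped this pattern. A lower share of muscle fibre RNA, as the only change, would raise the markers of every other cell type. In aged muscle macrophage markers exceeded endothelial markers by 1.13 ± 0.39 on the log2 scale (SD, n = 5, above 0 in 5 of 5 animals). Endothelial markers differed from young by a mean of -0.26, with aged replicate 4 above young (0.11). Macrophages and vessel cells may change in number by themselves, so this gap cannot tell whether the fibre share fell. A response of the fibres to age, or to changes that come with age such as denervation, may be another explanation and was not tested.

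Single probe sets were on or off in aged replicate 1, chosen by a gap of over 2.5 on the log2 scale from the other aged animals, which lay within 1.2 of each other. There were 6 in this animal, 2 in aged replicates 2 and 5, 1 in aged replicate 4 and young replicate 2 and none in the other 5 arrays; those with a gene symbol were Tor3a (5.34, against 8.37 to 8.59 in the other aged animals), Mrpl43 (5.97, against 8.98 to 9.90), Ccr2 (6.21, against 3.22 to 3.59) and Fcrl2 (7.4, against 3.75 to 4.11). A weaker age response was argued against for 4 of the 6, Tor3a, Ccr2, Fcrl2 and an unnamed one, whose level lay outside all other arrays by over 1 on the log2 scale. For Mrpl43 (5.97) this animal lay within the range of the young animals (5.78 to 6.39), from which the other aged animals stood apart. The same held for another unnamed probe set (6.25, young 5.88 to 6.38, other aged 2.09 to 2.37). A sequence variant under a probe, possible in outbred rats, cannot be told apart from a change in transcript level without genotypes, and 4 other arrays also had such probe sets. For Ccr2 and Fcrl2, receptors of leukocytes, the higher level went along with this animal's macrophage shift.

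Other animals passed the same criterion for single values. Young replicate 3 stood apart for Ddit4 (8.0, against 9.37 to 9.92 in the other young animals), Psmb9 (6.46, against 6.08 to 6.16), Pcna (9.34, against 9.27 to 9.29), Mrpl45 (9.79, against 9.60 to 9.66) and the MHC class I shift (0.21, against -0.09 to -0.01). Young replicate 1 stood apart for Trim63 (11.06, against 11.24 to 11.30) and the citric acid cycle shift (-0.09, against 0.01 to 0.04). Young replicate 2 stood apart for Fbp2 (9.81, against 10.71 to 10.92) and the T and NK cell shift (-0.08, against 0.01 to 0.03), and young replicate 5 for Postn (6.17, against 7.18 to 7.51). Aged replicate 5 stood apart for Psmb9 (9.34, against 7.30 to 7.87) and Gbp2 (8.93, against 6.64 to 7.17), and aged replicate 3 for Fbxo32 (6.23, against 6.92 to 7.16).

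Of all splits of the 10 arrays into 5 and 5, 100 were drawn, the real one included. In 1 of the 100, the real split, as many probe sets passed (6536, against at most 15 in the others). In 1 of the 100 as many passed at 1.5-fold (2299, against at most 15). For both counts this is the smallest share that 100 splits can give, so chance is unlikely but not excluded. The other splits mix ages within each side, so the age difference adds to their error and lowers their counts. For the lists, 3 of the 100 splits, the real one included, gave as many calls by camera at the preset correlation. The real split gave 25 and the others at most 27, with a median of 14. This share lies under 0.05, but other splits reached the same number, so chance is not excluded for the number of lists. No split of 5 and 5 balances the ages, so part of the age shift stays in each, but with age group as a term of the fit the other splits still gave a median of 13 lists, which argues against that shift as the whole cause of these calls. Genes of a list that vary together between animals may be another. Estimated correlations within lists reached 0.748 (proteasome), and with them camera called 0 lists in the real split. The other splits were not run with estimated correlations, so the share of their calls that comes from this is not known.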

How the results depend on the processing

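The fits without the 2 replacement columns were chosen after the data were seen, and the other alternatives were planned. Both counts of probe sets stayed within 1.5 times of 6536 and 2299 under all alternatives that count probe sets. Without single arrays they ran from 5117 (without aged replicate 5) to 7627 (without aged replicate 1) and from 2046 to 2872. The other alternatives gave 4520 (without the replacement columns) to 7201 (array weights), and 1918 (without the replacement columns) to 2407 (array weights). Fits of 1 value per gene count genes, with p adjusted over genes alone, and gave 4620 with the brightest probe set and 4382 with the mean over probe sets. Quantile normalization kept 5547 of the 6536 calls but turned the balance to 3057 higher and 3334 lower, whereas median centring gave 3973 higher and 2330 lower. Camera called 23 to 29 lists under the other alternatives, 22 to 28 without single arrays and 0 with an estimated correlation. The estimated correlations, up to 0.748 for the proteasome, widen the error of a list mean by construction. The log2 spread ratio of 0.171 was 0.392 among probe sets brighter than the median, where it passed. The cause of this higher ratio was not tested. Over all probe sets the ratio was -0.017 without the replacement columns, 0.075 to 0.168 without single aged arrays and 0.2 to 0.279 without single young arrays. SDs of fewer arrays tend to come out smaller, so groups of unequal size shift the ratio. These values can therefore not be set against 0.171 directly.

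Values near 0 turned sign, and the cause was not tested. The log2 fold change of Fbxo32 was -0.009 with quantile normalization, -0.035 without the replacement columns and -0.005 to 0.239 without single arrays. The mean of the heat shock list was 0.03 with median centring, 0.005 with array weights, 0.008 without the replacement columns and -0.049 to 0.069 without single arrays. That of the atrophy ligases was -0.06 with quantile normalization, -0.002 with array weights, -0.022 without the replacement columns and -0.033 to 0.037 without single arrays. Of 172 named genes, 167 kept their direction and side of the threshold with quantile normalization, 170 with median centring and 150 without the replacement columns, where 20 calls were lost. Without single arrays, 1643 of 1720 gene values did so and 74 calls were lost, 63 of them in the 25 list members that the text groups apart. The mean over probe sets made the log2 fold change of 23 of 44 called genes with several probe sets smaller by over 1.5 times, for example 0.69 against 1.96 for Postn, -0.29 against -0.83 for Myh1, 1.08 against 2.28 for Gsta3 and 1.70 against 3.59 for RT1-CE5, and of these 1 call was lost (Igha). The smaller of the 2 counts of a list moved over 1.5 times by at least 2 genes in 4 lists, given with them, and by 1 gene in 17 others when arrays were left out.

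Replicate numbers did not pair the animals: deviations of same-numbered arrays correlated between -0.117 and 0.027, and 1 of 10 arrays correlated best with its own number. With the replicate number as a block, 5551 probe sets, 2282 at 1.5-fold and 29 lists passed, among them 4 lists that did not pass without it. Of the named genes, Fos passed (adjusted p = 0.00736) and Blk, Cma1 and Col3a1 did not (adjusted p = 0.0553, 0.0554 and 0.0696). No measure of signal over background came with the arrays, so no limit from it could be set.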

Other observations

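The groups described in these paragraphs were chosen after the decreases of Nr4a3, Nr4a1, Apold1, Dusp1 and Tfrc had been seen.

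Immediate-early genes, which cells switch on within minutes of a stimulus such as contraction, were split in aged muscle. Of 30 measured genes of a list written for this purpose, 8 fell and 5 rose at an adjusted p under 0.05 in limma's fit. Beside Nr4a3, Nr4a1, Apold1 and Dusp1, the RNA-binding protein gene Zfp36 fell 2.82-fold (log2 fold change -1.5 ± 0.22, adjusted p = 0.000655), and the transcription factor genes Klf4 and Klf2 fell 2.17-fold and 1.63-fold. In the other direction Myc rose 2.99-fold (log2 fold change 1.58 ± 0.14, adjusted p = 3.62e-05), the AP-1 subunit gene Junb 2.10-fold and the kinase gene Sik1 2.01-fold. Fos was 2.58-fold lower but did not pass (log2 fold change -1.37 ± 0.54, adjusted p = 0.116). The hypothesis that immediate-early genes were lower as a group, as they might be if aged animals had moved less before tissue was taken, stays open. Camera at the preset correlation gave p = 0.154, the mean log2 fold change was -0.33 and the median -0.04, and the list was written after 4 of its falling members had been seen.

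Iron handling genes moved in both directions beside the fall of Tfrc. Ftl1, the light chain of the iron store ferritin, rose 3.22-fold (log2 fold change 1.69 ± 0.16, adjusted p = 4.84e-05), Hmox1, which releases iron from haem, 3.11-fold and the iron exporter Slc40a1 1.90-fold. The ferritin heavy chain gene Fth1 had a log2 fold change of -0.13 ± 0.06 that did not pass (adjusted p = 0.142). In this list 4 of 10 genes rose and 2 fell. In limma's fit, camera at the preset correlation did not call iron handling (p = 0.203).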
